A study of Homo sapiens with 6 samples.

How the data were processed

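RNA of sorted ST486 cells carrying a control shRNA, ZDHHC11 shRNA 1 or ZDHHC11 shRNA 2, with 2 arrays per group, had been isolated with miRNeasy and hybridised to Agilent arrays of 62976 spots, labelled with Cy3 only. The scanner files are deposited as Agilent Feature Extraction 12.0.1.1 output (protocol GE2_1200_Jun14), and per the file headers the processed and background-subtracted signals are intensity values with other columns holding 0 or 1 quality calls, on a probe design annotated to hg19. The protocol is for 2 colours, so the processed signal was dye-normalized against a red channel in which no sample was hybridised. The value table deposited by the authors holds log2 values of the processed signal, quantile-normalized between the 6 arrays as judged from the values; the labels do not give the steps. All 6 arrays were on 1 slide; replicate 1 of each group was in slide row 1 and replicate 2 in row 2. The 75th percentile of background-subtracted signal was 228 and 147 for control replicates 1 and 2, 221 and 147 for shRNA 1, and 263 and 177 for shRNA 2. No spot was saturated, and 50 to 80 outlier spots per array were left out.

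The following was fixed before the data were examined. The settings fixed beforehand used log2 processed signal minus its 75th percentile on each array, spots of a probe averaged, without control spots and outlier spots, and probes well above background on at least 2 of 6 arrays (28042 probes). All 6 arrays entered 1 limma fit with 3 group means and no further terms, with 3 residual degrees of freedom, and each contrast was tested with eBayes moderation, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The contrasts were shRNA 1 against control, shRNA 2 against control, the mean of both against control, and shRNA 2 against shRNA 1. Gene lists, 34 in number, were tested with camera on the moderated statistics with a preset correlation of 0.01, adjusted over all lists and the 3 comparisons with control; the comparison between the shRNAs was adjusted over its own lists. Each list was also tested with an estimated correlation and with fry. The test with an estimated correlation rests on the 3 residual degrees of freedom, so a list could hardly pass it.

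The second settings were not fixed beforehand. Before any test the processed signal was judged compressed from the columns alone, and background-subtracted signal, scaled to the 75th percentile with a floor of 0.116 of it (−3.11 on the log2 scale), was added. After counts of passing genes had been seen under up to 19 settings, the filter was changed to probes well above background on all 6 arrays (23045 probes), since values held at the floor distort the shared estimate of the spread. The prior degrees of freedom were 3.36 with the settings fixed beforehand and 6.49 with the second settings. This filter leaves out genes that are switched on or off between groups, which are given as lower bounds against the floor.

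Probes were named through their RefSeq accessions, which gave 31104 of 58201 probes a gene symbol; the remainder, among them 11968 long non-coding RNA probes and 9747 Ensembl transcript probes, were tested as probes and not counted as genes. A gene was counted once, by its brightest tested probe. The gene naming rule, fixed beforehand, took ZDHHC11, ZDHHC11B, MYB and MYC, the 6 highest and 6 lowest passing genes per comparison, the 12 highest and 12 lowest passing with both shRNAs, and up to 4 members per list. Where fewer than 5 genes passed, the 10 with the smallest p were named. The rule was applied to the second settings after their values had been seen, not every gene it takes is printed, and list members beyond the rule, such as ZDHHC2, RGS13, BIRC3 and ICAM1, were chosen after their values were seen.

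Overlap and correlation of both shRNAs were set against 100 simulations of unchanged groups with shared controls. Alternatives were normexp background correction with an offset of 50 (on median in place of mean spot signal, which the files lack), quantile normalization, the deposited value table, no filter, the filter on all 6 arrays, replicate number as a block, only the groups compared, an intensity trend with robust eBayes, a log2 threshold of 1, and leaving out each array. The method was tested on simulated data with 200 genes changed at each of the sizes 0.5, 1 and 2, on the log2 scale of the settings tested. With shRNA 1 against control, a change of 1 was recovered for 82.8% of genes with the settings fixed beforehand and 91.2% with the second settings. A change of 0.5 was recovered for 6.33% and 12%, and false calls made up 2.15% and 4.02%. As the processed signal is compressed, the same true change is smaller on its scale, so rates cannot be compared between the settings. The simulated noise was drawn independently from moderated variances, which are more even across probes than the measured spread. Recovery on the real arrays may thus be lower, and few calls there do not show that few genes changed. The software was R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with matplotlib 3.10.9. The shRNA sequences were not used here.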

Results

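Gene expression was measured in ST486, an established Burkitt lymphoma cell line, after ZDHHC11 had been knocked down with either of 2 short hairpin RNAs (shRNAs). ZDHHC11 belongs to a family of enzymes that attach palmitate to proteins, and both shRNAs were directed against all of its transcripts. A lentiviral vector carried the shRNA together with a red fluorescent protein, and the red fluorescent cells were sorted before RNA was isolated. The RNA was hybridised to 6 arrays with probes for mRNAs and long non-coding RNAs, 2 arrays for a control shRNA, 2 for ZDHHC11 shRNA 1 and 2 for ZDHHC11 shRNA 2. Of 58201 probes, 42.6% to 47.8% were well above background on each array. The number of arrays limits the precision, and since nothing states that the replicates were separate cultures, p-values measure only the spread between these samples, which may be technical. The first principal component, with 49.0% of the variance, set the shRNA 2 arrays apart. The second (23.1%) parted control from shRNA 1, and the third (12.5%) followed the replicate numbers. The processed signal of the scanner software rose by 0.598 to 0.619 on the log2 scale per unit of log2 background-subtracted signal, so fold changes taken from it are compressed. Counts are given first with the settings fixed beforehand, which use the processed signal. Gene and gene list values come from a second set of settings (the second settings) with background-subtracted signal and probes well above background on all 6 arrays, adopted after the counts of passing genes had been seen.

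ZDHHC11 was lower on all 4 arrays with an shRNA against it than on both control arrays. On the log2 scale relative to the 75th percentile of each array, it read 3.16 ± 0.12 (SD, n = 2) with the control shRNA, 1.32 ± 0.46 with shRNA 1 and 1.90 ± 0.18 with shRNA 2. ZDHHC11 thus changed by a log2 fold change of −1.84 (SE 0.229, adjusted p = 0.00679) with shRNA 1, which is 3.58-fold lower. With shRNA 2 it changed by −1.26 (SE 0.229, adjusted p = 0.0127), which is 2.39-fold lower. A second ZDHHC11 probe fell by 1.63 with shRNA 1 and by 1.21 with shRNA 2, and the remaining ZDHHC11 probes lay near background. The depth of the knock-down did not pass as different between the shRNAs (ZDHHC11 0.58 higher with shRNA 2, adjusted p = 0.122). With the settings fixed beforehand ZDHHC11 read −1.20 (adjusted p = 0.128) and −0.82 (adjusted p = 0.098), neither of which passed. Over 16 alternatives to those settings ZDHHC11 stayed lower throughout, from −1.84 to −1.07 with shRNA 1 and from −1.26 to −0.73 with shRNA 2. The adjusted p ran from 2.08e-06 to 0.695 and from 0.00055 to 0.42. With the second settings the shRNA 1 call was lost without shRNA 1 replicate 2 (−1.51). The shRNA 2 call was lost without control replicate 1 (−1.17) or shRNA 2 replicate 2 (−1.13). ZDHHC11B, a nearly identical copy of ZDHHC11, has no probe of its own and was not analysed separately here. Whether the ZDHHC11 probes also read ZDHHC11B was not tested, so the values for ZDHHC11 may be of both genes.

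MYB and MYC were read because ZDHHC11 transcripts have been described in Burkitt lymphoma as binding miR-150, a microRNA that represses the transcription factor MYB. MYB did not change detectably, with log2 fold changes of −0.26 (adjusted p = 0.538) for shRNA 1 and 0.30 (adjusted p = 0.279) for shRNA 2. MYC, the transcription factor activated by translocation in Burkitt lymphoma, read 5.28 ± 0.18 with the control shRNA, 4.29 ± 0.19 with shRNA 1 and 5.25 ± 0.02 with shRNA 2 (SD, n = 2). MYC was lower with shRNA 1 (−0.99, SE 0.179, adjusted p = 0.0286) and not with shRNA 2 (−0.03, adjusted p = 0.927). The difference between the shRNAs itself passed (0.95, SE 0.179, adjusted p = 0.00971). The MYC call with shRNA 1 was lost without any 1 of the 6 arrays, where MYC read −1.12 to −0.85. The difference in MYC between the shRNAs was lost without shRNA 1 replicate 2 (0.82) or shRNA 2 replicate 2 (0.94). With the settings fixed beforehand MYC read −0.59 (adjusted p = 0.227) and −0.07 (adjusted p = 0.796).

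**Figure D1:**
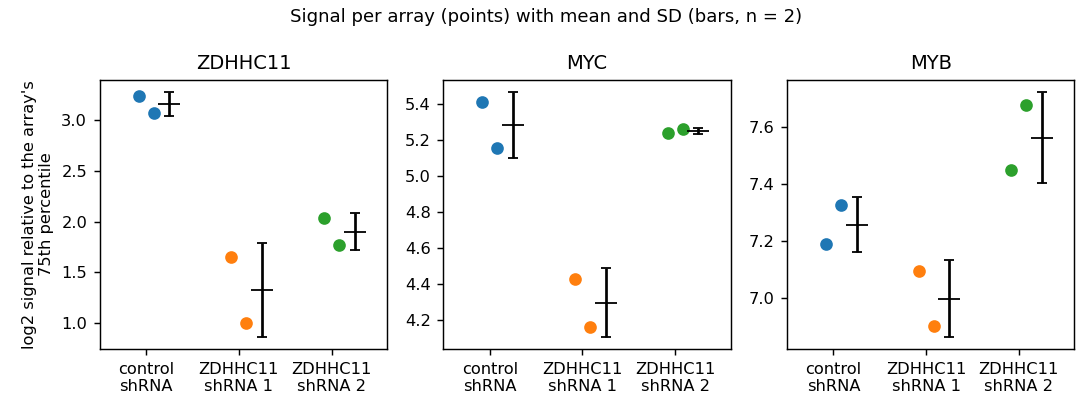
Levels of ZDHHC11, MYC and MYB on each of the 6 arrays (points) with the mean and SD of each group (n = 2), as log2 signal relative to the 75th percentile of the array, each panel on its own axis. ZDHHC11 lies between 0.99 and 2.03 on the 4 arrays with an shRNA against it and at 3.08 and 3.25 on the control arrays.

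With shRNA 1, BCL6, the repressor that maintains the germinal centre state, had a log2 fold change of −2.10 (SE 0.253, adjusted p = 0.00651), a 4.29-fold fall. MEF2B, an activator of BCL6, changed by −1.68 (adjusted p = 0.00435). STK26, a kinase of cell polarity, changed by −2.33 (SE 0.167, adjusted p = 0.00283), and CLDN16, a tight junction protein, by −2.45 (adjusted p = 0.00315). KIF19, a motor protein, changed by −2.27 (adjusted p = 0.0154) and TMEM123, a surface protein, by −1.95 (adjusted p = 0.00311). BCAT1, which breaks down branched-chain amino acids, changed by −1.99 (adjusted p = 0.00311) on its brightest probe and by −0.81 (adjusted p = 0.0471) on another. The largest rises were those of COL24A1, a collagen (2.25, SE 0.215, adjusted p = 0.00311), the HLA-region transcript HCG26 (2.25, adjusted p = 0.00311) and the lymphocyte transcription factor KLF2 (2.03, adjusted p = 0.00435). They were followed by the chemokine CCL3 (1.98, adjusted p = 0.00435), VCX2 of the VCX family (1.84, adjusted p = 0.00311) and the vault protein MVP (1.79, adjusted p = 0.0169). Control means of COL24A1 (−2.55) and VCX2 (−2.43) lay toward the floor of −3.11, so the size of their rises is uncertain. ZDHHC2, another enzyme of the ZDHHC family, also fell, by 1.93 on the log2 scale (adjusted p = 0.00474). ZDHHC2 did not pass with shRNA 2 (0.38, adjusted p = 0.377), and the difference between the shRNAs passed (2.31, adjusted p = 0.00111).

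With shRNA 1 and the settings fixed beforehand, limma called 0 of 14296 genes, although 1585 had an unadjusted p below 0.05 against 715 by chance. The smallest adjusted p was 0.108. The 10 genes with the smallest p, none of which passed, were RNASE6, IFITM1, ADAMTS18, CCR1 and VCX2 (higher) and STK26, RSPO4, TMEM123, PSAT1 and BCAT1 (lower). RNASE6, a secreted ribonuclease, was well above background on both shRNA 1 arrays and at least 1.71-fold higher than in control. With normexp background correction, an alternative written down beforehand, 287 genes passed. With the second settings 255 of 12705 genes passed, 92 higher and 163 lower, and 2052 had an unadjusted p below 0.05. All 255 changed in the same direction with the settings fixed beforehand. The count became 108 without control replicate 1, 85 without control replicate 2, 30 without shRNA 1 replicate 1 and 1 without shRNA 1 replicate 2, and 86, 70, 30 and 0 of the 255 were among these. Of the 30 genes named for this comparison, limma called 0 without shRNA 1 replicate 2, where STK26 read −2.24, BCL6 −1.92 and COL24A1 2.46.

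Genes of the ATF4 amino acid response fell together with shRNA 1 (median log2 fold change −0.56 over 24 genes, camera adjusted p = 1.69e-10, adjusted p = 0.782 with an estimated correlation). PSAT1, which makes serine, changed by −1.43 and the transcription factor CEBPG by −1.13. These were the 2 genes of the list that passed over all genes, against 14 adjusted over the list alone, all lower. The ATF4 median was −0.36 without control replicate 2. MHC class II genes, which present antigen, were also lower (median −0.48 over 15 genes, adjusted p = 4.83e-05, adjusted p = 0.782 with an estimated correlation). By limma 0 of 15 passed as lower over all genes and 9 adjusted over the list alone, HLA-DOA being the lowest at −0.74. CTSS, a protease of antigen processing on that list, passed as higher (0.88). The germinal centre list had a median of −0.15 over 23 genes (adjusted p = 0.00113, adjusted p = 0.782 with an estimated correlation), with 4 lower and 1 higher, and 9 lower and 1 higher adjusted over the list alone. RGS13, a regulator of chemokine signalling, changed by −1.68, while S1PR2, a receptor that holds cells in the follicle, rose by 1.58. The germinal centre median was −0.24 without control replicate 2. NF-kB targets were lower (−0.21 over 19 genes, adjusted p = 0.00669, adjusted p = 0.782 with an estimated correlation). BIRC3 at −1.20, RELB at −1.16 and TNFAIP3 at −0.96 were the 3 lower calls and CCL3 the 1 higher call, with 6 lower and 1 higher adjusted over the list alone, and the median was −0.32 without shRNA 1 replicate 1. Interferon response genes were higher (0.31 over 26 genes, adjusted p = 6.91e-05, adjusted p = 0.782 with an estimated correlation), USP18 and IFIT1 among them, with 4 higher over all genes and 6 higher and 1 lower adjusted over the list alone. B lineage genes were slightly lower (−0.22 over 24 genes, adjusted p = 0.0235, adjusted p = 0.862 with an estimated correlation). FCRL2 at −1.29 was the 1 call over all genes, with 2 lower adjusted over the list alone, and the list was lost without control replicate 1 (−0.11) or shRNA 1 replicate 2 (−0.07). Cholesterol synthesis genes were higher (0.27 over 23 genes, adjusted p = 0.00138, adjusted p = 0.862 with an estimated correlation). By limma 0 of them passed over all genes or adjusted over the list alone, and the list was lost without control replicate 1 (0.07), whereas it read 0.49 without control replicate 2. G2/M genes were higher (0.19 over 42 genes, adjusted p = 0.0354, adjusted p = 0.863 with an estimated correlation), a call lost without control replicate 1 (0.16) or shRNA 1 replicate 1 (0.11). The 1 gene that passed over all genes as well as adjusted over the list alone was the spindle gene TPX2, which was lower.

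**Figure D2:**
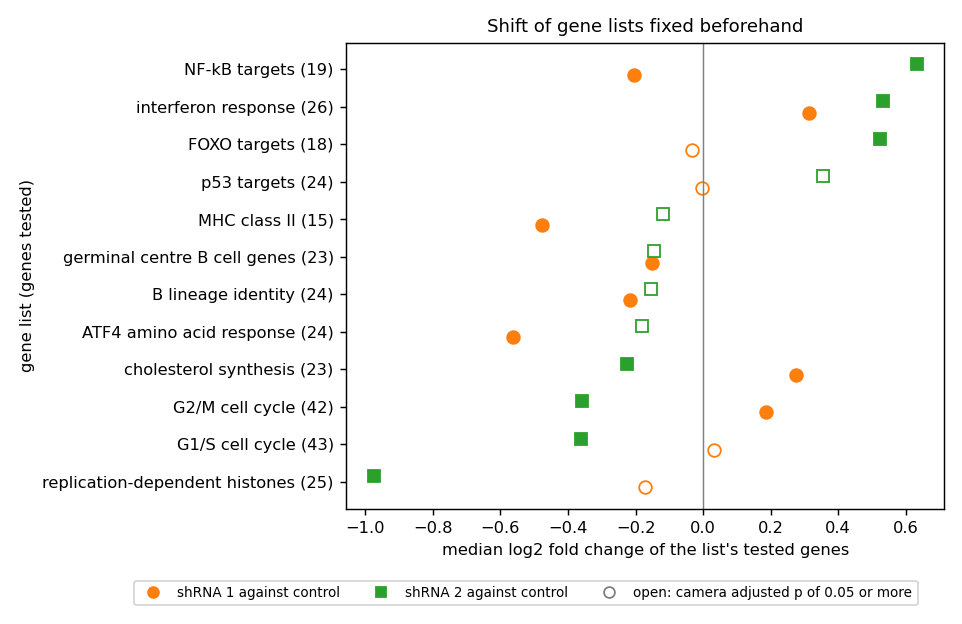
Median log2 fold change against control of 12 gene lists with shRNA 1 and with shRNA 2, where filled points passed (camera adjusted p below 0.05 with a preset correlation), open points did not. Histone genes lie at −0.98 with shRNA 2, and NF-kB targets at −0.21 with shRNA 1 and 0.63 with shRNA 2.

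With shRNA 2, DUSP26, a phosphatase, rose by a log2 fold change of 4.43 (SE 0.387, adjusted p = 0.0028). Its control arrays read −2.22 and −1.03, and it rose by 3.83 without control replicate 1 and by 5.02 without control replicate 2. Next came AMBP, a secreted protease inhibitor precursor (2.98, SE 0.322, adjusted p = 0.0036), and TMEM229B, a membrane protein (2.93, SE 0.383, adjusted p = 0.00485). TMEM229B rose by 3.68 without shRNA 2 replicate 1 and by 2.17 without shRNA 2 replicate 2. PTCRA, a T cell receptor chain (2.77, adjusted p = 0.00689), FAM177B, a gene with little described function (2.76, adjusted p = 0.0159), and TP53INP1, a stress gene induced by p53 (2.76, adjusted p = 0.0036), rose as well. PTCRA rose by 1.98 without control replicate 1 and by 3.55 without control replicate 2. The largest falls were those of KIF19 (−2.23, adjusted p = 0.00801), TRAF3IP3, an adaptor in lymphocyte signalling (−2.20, adjusted p = 0.00364), and WNK2, a kinase (−1.98, adjusted p = 0.00455). A second, dimmer WNK2 probe read −0.49 and did not pass (adjusted p = 0.0788). They were followed by the ribosomal RNA RNA18SN5 (−1.95, adjusted p = 0.011), the long non-coding RNA OLMALINC (−1.93, adjusted p = 0.0245) and CDK14, a cyclin-dependent kinase (−1.85, adjusted p = 0.00407). STK26 and BCL6, both lower with shRNA 1, did not pass here (−0.10 and −0.45). The difference between the shRNAs passed for STK26 (2.23, adjusted p = 0.000609) and for BCL6 (1.65, adjusted p = 0.00485).

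With shRNA 2 and the settings fixed beforehand, limma called 1 of 14296 genes, CALD1, an actin-binding protein, at 2.93 (SE 0.151, adjusted p = 0.0188). By comparison 2798 genes had an unadjusted p below 0.05 against 715 by chance. CALD1 was not well above background on any control or shRNA 1 array and was at least 5.10-fold higher with shRNA 2. Its call was lost without any 1 of the 6 arrays, the count being 0 each time, while CALD1 read 2.85 to 3.02 (adjusted p = 0.062 to 0.342). The other 9 genes with the smallest p, none of which passed (adjusted p = 0.0781), were RNF122, COL24A1, CCL3, FAM53B, LINC01882, FRMD3, NFAM1, BRMS1L and SKIDA1, all higher. With normexp 1347 genes passed. With the second settings 1602 of 12705 passed, 908 higher and 694 lower, of which 1595 changed in the same direction with the settings fixed beforehand. The count became 783 without control replicate 1, 367 without control replicate 2, 965 without either shRNA 1 array and 36 without shRNA 2 replicate 2, and 645, 342, 955 and 35 of the 1602 were among these. Without shRNA 2 replicate 2, 5 of 34 named genes still passed, namely DUSP26, TMEM229B, COL24A1, CCL3 and SNORA12. Among the genes lost, AMBP read 2.93, TP53INP1 2.39, KIF19 −2.24 and TRAF3IP3 −1.86. FAM177B, whose control arrays read 1.08 and −1.08, changed by 3.84 without control replicate 1 and by 1.68 without control replicate 2. RNA18SN5 was also lost without control replicate 2 (−1.46), and OLMALINC without control replicate 2 (−1.11) or shRNA 2 replicate 1 (−1.95). OLMALINC read −2.74 without control replicate 1.

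Replication-dependent histone genes, which are transcribed in S phase, had a median log2 fold change of −0.98 over 25 genes with shRNA 2 (camera adjusted p = 6.94e-15, adjusted p = 0.204 with an estimated correlation). Of these 21 were lower and 1 higher over all genes, and 24 lower and 1 higher adjusted over the list alone. H3C2 changed by −1.44, H4C8 by −1.33 and H1-4 by −1.29. The 1 higher call was H2BC12, whose probes moved in opposite directions, by 1.66 on the brighter and −0.90 on the other. G1/S genes were lower (−0.36 over 43 genes, adjusted p = 3.47e-07, adjusted p = 0.862 with an estimated correlation). There were 11 lower over all genes and 14 adjusted over the list alone, among them the replication genes CDC45 (−0.90), MCM7 (−0.85) and BRIP1 (−0.82). G2/M genes were lower too (−0.36 over 42 genes, adjusted p = 4.55e-06, adjusted p = 0.862 with an estimated correlation). There were 3 calls over all genes, CDCA3 at −1.07 being the largest, and 1 adjusted over the list alone. NF-kB targets rose (0.63 over 19 genes, adjusted p = 6.6e-05, adjusted p = 0.782 with an estimated correlation). There were 9 higher over all genes and 10 adjusted over the list alone, including the adhesion molecule ICAM1 (1.32), the apoptosis inhibitor BIRC3 (1.25) and the NF-kB cofactor BCL3 (2.24). Interferon response genes rose (0.53 over 26 genes, adjusted p = 6.82e-05, adjusted p = 0.782 with an estimated correlation). There were 11 higher over all genes and 14 adjusted over the list alone, including the antiviral genes IFIT1 (1.42), BST2 (1.26) and OAS1 (1.17). FOXO targets rose (0.52 over 18 genes, adjusted p = 0.00113, adjusted p = 0.782 with an estimated correlation). There were 8 higher over all genes and 9 higher and 1 lower adjusted over the list alone, including the autophagy gene GABARAPL1 (1.53), the mitochondrial kinase PINK1 (1.16) and the glucose uptake inhibitor TXNIP (1.07). Cholesterol synthesis genes were lower (−0.23 over 23 genes, adjusted p = 0.0235, adjusted p = 0.862 with an estimated correlation). ACAT2 (−0.88) and FDPS (−0.77) were the 2 calls over all genes, with 2 adjusted over the list alone. That list was lost without control replicate 2 (−0.01) or shRNA 2 replicate 1 (−0.10) and read −0.45 without control replicate 1. With the settings fixed beforehand 5 further lists passed with shRNA 2. They were B lineage genes (adjusted p = 0.0156, adjusted p = 0.616 with an estimated correlation), ribosomal proteins (median 0.15, adjusted p = 0.00878, adjusted p = 0.863 with an estimated correlation) and immediate early genes (adjusted p = 0.0212, adjusted p = 0.616 with an estimated correlation). The others were p53 targets (adjusted p = 0.0269, adjusted p = 0.635 with an estimated correlation) and snoRNA host genes (adjusted p = 0.0292, adjusted p = 0.616 with an estimated correlation). The ribosomal protein median was −0.05 with the second settings.

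Among the genes that passed the same way with both shRNAs, COL24A1 rose by 2.25 and 2.41 on the log2 scale with shRNA 1 and shRNA 2, CCL3 by 1.98 and 2.46 and MVP by 1.79 and 2.44. Rises were also seen for the antibody gene recombinase RAG1 by 1.75 and 1.65, the antiviral gene IFIT1 by 1.65 and 1.42 and KLF2 by 2.03 and 1.32. KIF19 changed by −2.27 and −2.23, WNK2 by −1.39 and −1.98, FAM107B by −1.32 and −1.59 and CLDN16 by −2.45 and −1.15. The B cell transcription factor BCL11A changed by −1.24 and −1.15, the B cell transcription factor IRF8 by −1.51 and −1.02 and the cysteine-producing enzyme CTH by −1.27 and −1.10. Without control replicate 2, 11 of 30 named genes were lost with shRNA 1 and 7 of 34 with shRNA 2. Among them were CTH (−0.87 and −0.69), NLRP11 (−1.13 and −0.62), SLC6A9 (−1.01 and −0.88), BCL11A (−1.27 and −1.18) and, with shRNA 2, CLDN16 (−0.78). KIF19 passed there at −1.62 and −1.59 and read −2.91 and −2.88 without control replicate 1. It was lost with shRNA 1 without either shRNA 1 array (−2.12 and −2.41), and with shRNA 2 without shRNA 2 replicate 2. IRF8 with shRNA 2 was lost without control replicate 1 (−0.83). Of the named genes, 0 of 30 with shRNA 1 and 5 of 34 with shRNA 2 passed whichever array was left out. Other probes did not pass with shRNA 1 for BCL11A (−0.91) and FAM107B (−0.94) or with shRNA 2 for WNK2 (−0.49). USP18, a protease of the interferon pathway, ANK3, PAQR9-AS1 and the small nucleolar RNAs SNORA12 and SNORD116-11 also passed as higher with both shRNAs, and SCN4A, RIOX2, NLRP11 and SLC6A9 as lower. Control means lay toward the floor of −3.11 for COL24A1 (−2.55), RAG1 (−2.09), SNORA12 (−2.12), ANK3 (−2.84), PAQR9-AS1 (−2.815) and SNORD116-11 (−2.88). The size of these rises is thus uncertain, COL24A1 with shRNA 1 ranging from 1.14 to 2.46 over alternatives. Control means were higher for MVP (0.54), IFIT1 (0.45), KLF2 (0.27) and USP18 (0.20). As the mean of both shRNAs, COL24A1 changed by 2.33 (SE 0.186, adjusted p = 0.00411) and CCL3 by 2.22 (SE 0.179, adjusted p = 0.00411). In the same mean IRF8 changed by −1.26 (SE 0.169, adjusted p = 0.0114) and KIF19 by −2.25 (SE 0.296, adjusted p = 0.0113).

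With the second settings 72 genes passed with both shRNAs in the same direction, 48 higher and 24 lower, and 14 passed in opposite directions. Independent lists would share 15.5 in the same direction, a value that leaves the shared controls out. The 100 simulations of unchanged groups with shared controls gave 0.03 on average, since few genes pass at all in such groups. Neither gives the overlap to expect from changed lists that share controls, so how much of the 72 is common to both shRNAs was not tested. For the mean of both shRNAs 337 genes passed, 200 higher and 137 lower, 129 of them by at least 1 on the log2 scale. With the settings fixed beforehand limma called 0 genes with both shRNAs and 0 for the mean (smallest adjusted p = 0.0562, for CALD1), where 1935 genes had an unadjusted p below 0.05. Normexp gave 74 and 407. The count with both shRNAs became 40 without control replicate 1, 24 without control replicate 2, 9 without shRNA 1 replicate 1, 0 without shRNA 1 replicate 2 and 5 without shRNA 2 replicate 2, and 22, 18, 9, 0 and 4 of the 72 were among these. The count for the mean became 88 and 42 without control replicates 1 and 2, 51 and 65 without shRNA 1 replicates 1 and 2 and 6 without shRNA 2 replicate 2, and 64, 39, 50, 61 and 6 of the 337 were among these. Across genes, which are not independent replicates, the fold changes with shRNA 1 and shRNA 2 had a Pearson correlation of 0.385 with the settings fixed beforehand and 0.304 with the second settings. Simulated unchanged groups gave 0.499 and 0.501, because both comparisons share their controls. Their covariance, 0.0502 with the second settings, exceeded the simulated 0.0197. A check chosen after the data were seen gave each shRNA 1 control array of its own, so that none was shared. With control replicate 1 for shRNA 1 and control replicate 2 for shRNA 2 the Pearson correlation was 0.0873 with the settings fixed beforehand and 0.0915 with the second settings. With the control arrays exchanged it was 0.144 and 0.163. The covariance with the second settings was 0.0178 and, exchanged, 0.0306, against 0.0502 with shared controls. Averaged over both assignments such a fall follows from the arithmetic, and the control arrays also lay in different slide rows. How much of the 0.0502 came from sharing the controls was therefore not tested. Anything common to both control arrays stays in both comparisons.

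As the mean of both shRNAs, histone genes had a median of −0.54 (camera adjusted p = 3.96e-12, adjusted p = 0.204 with an estimated correlation). There were 2 lower and 1 higher over all genes and 22 lower and 1 higher adjusted over the list alone. Interferon response genes rose by a median of 0.45 (adjusted p = 7.9e-07, adjusted p = 0.782 with an estimated correlation). There were 4 higher over all genes and 13 adjusted over the list alone, USP18 (1.85), IFIT1 (1.53) and IFIT3 (1.14) among them. ATF4 genes changed by −0.30 (adjusted p = 5.39e-07, adjusted p = 0.862 with an estimated correlation), with 3 lower over all genes, PSAT1, CEBPG and MTHFD2, and 6 adjusted over the list alone. G1/S genes passed as lower (−0.20, adjusted p = 0.000329, adjusted p = 0.862 with an estimated correlation), as did MHC class II (−0.28, adjusted p = 0.00155, adjusted p = 0.833 with an estimated correlation). Germinal centre genes passed (−0.15, adjusted p = 0.00425, adjusted p = 0.786 with an estimated correlation), as did B lineage genes (−0.15, adjusted p = 0.0242, adjusted p = 0.862 with an estimated correlation). Of these lists only interferon response genes also passed with each shRNA by itself with the second settings. Histone and G1/S genes passed with shRNA 2 and not shRNA 1. ATF4, MHC class II, germinal centre and B lineage genes passed with shRNA 1 and not shRNA 2. For these lists the mean therefore does not show a response shared by both shRNAs. In limma 0 G1/S genes passed over all genes or adjusted over the list alone. For MHC class II 0 passed over all genes and 4 lower and 1 higher adjusted over the list alone. Germinal centre genes had 3 lower and 1 higher over all genes, BCL6, MEF2B and S1PR2 among them, and 7 lower and 1 higher adjusted over the list alone. B lineage genes had 3 lower and 4 lower adjusted over the list alone. Without control replicate 1 the G1/S (−0.09), germinal centre (−0.18) and B lineage (−0.11) lists were lost, and B lineage also without shRNA 1 replicate 2 (−0.05). The ATF4 median was −0.52 without control replicate 1 and −0.16 without control replicate 2, and that of the germinal centre list was −0.24 without shRNA 1 replicate 1. The G1/S median was −0.12 without shRNA 1 replicate 2 and −0.13 without shRNA 2 replicate 2, and the B lineage median was −0.24 without control replicate 2 and −0.10 without shRNA 2 replicate 2. Over the 3 comparisons with control 27 of 102 list tests passed with the settings fixed beforehand and 22 with the second settings, all 22 in the same direction in both. No list call held with an estimated correlation, in either settings. The smallest camera adjusted p of that test was 0.494 with the settings fixed beforehand and 0.204 with the second settings. With 3 residual degrees of freedom it had little power, so the loss does not show that correlation between genes explains the calls. Nor are the calls secured without it. Besides the 30 and 34 genes counted above, 0 of 13 others named with shRNA 1, 2 of 26 with shRNA 2 and 2 of 13 for the mean passed whichever array was left out, and none changed direction.

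**Figure D3:**
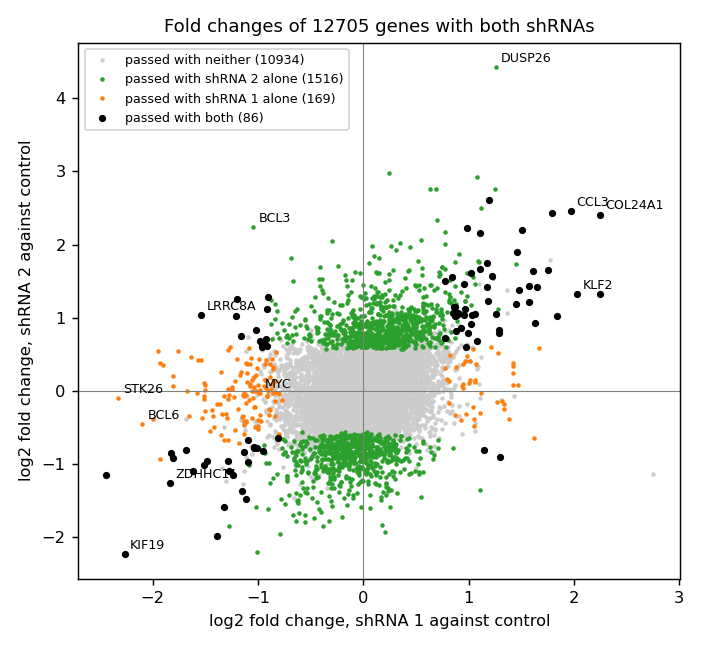
Log2 fold change against control with shRNA 1 (horizontal axis) and shRNA 2 (vertical axis) for 12705 genes, coloured by the comparisons in which they passed. There were 86 genes past the threshold with both shRNAs, 169 with shRNA 1 alone and 1516 with shRNA 2 alone.

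The shRNAs were compared directly to see where their effects parted, and several genes moved in opposite directions. LRRC8A, a subunit of the volume-regulated anion channel, changed by −1.54 with shRNA 1 and by 1.03 with shRNA 2, a difference of 2.58 (SE 0.173, adjusted p = 0.000537). BCL3 was 3.29 higher with shRNA 2 than with shRNA 1 (SE 0.258, adjusted p = 0.000743), DUSP26 3.17 (SE 0.387, adjusted p = 0.0021) and AMBP 2.73 (SE 0.322, adjusted p = 0.0019). IGFBP2, which binds insulin-like growth factors, was higher by 2.50 (adjusted p = 0.000609) and TMEM123 2.50 (adjusted p = 0.000609). Among the genes lower with shRNA 2, the differences were −2.46 for MEI1, a meiosis gene (adjusted p = 0.00246), and −2.26 for MEX3A, an RNA-binding protein (adjusted p = 0.0014). They were −2.19 for ATP6V1G2, a proton pump subunit (adjusted p = 0.000858), and −2.14 for OLMALINC (adjusted p = 0.0133). LINC01389 (−2.01, adjusted p = 0.00251) and the integrin ITGB2 (−2.01, adjusted p = 0.00285) came after these. In the NF-kB pathway BIRC3 differed by 2.45 (adjusted p = 0.00111), RELB by 1.92 (adjusted p = 0.0014) and TNFAIP3 by 1.60 (adjusted p = 0.00154), and each passed as lower with shRNA 1 and as higher with shRNA 2.

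Between the shRNAs limma called 5 of 14296 genes with the settings fixed beforehand. They were CALD1 (2.05, adjusted p = 0.0431), NFAM1 (1.72, adjusted p = 0.0443), LRRC8A (1.67, adjusted p = 0.0443) and TMEM123 (1.56, adjusted p = 0.0453) higher with shRNA 2 and RNASE6 lower (−2.22, adjusted p = 0.0431). CALD1 was at least 5.10-fold higher with shRNA 2 than with shRNA 1. All 5 calls were lost without any 1 array, the count being 0 each time. CALD1 then read 1.91 to 2.19, NFAM1 1.65 to 1.80, LRRC8A 1.55 to 1.78, TMEM123 1.45 to 1.67 and RNASE6 −2.39 to −2.06. With all 6 arrays 3027 genes had an unadjusted p below 0.05. With normexp 1676 genes passed. With the second settings 2012 passed, 1127 higher and 885 lower with shRNA 2, of which 2005 had the same sign with the settings fixed beforehand. The count became 683 without shRNA 1 replicate 1, 255 without shRNA 1 replicate 2 and 341 without shRNA 2 replicate 2, and 651, 253 and 336 of the 2012 were among these. Of the 12 genes that the naming rule took between the shRNAs and MYC, 11 passed whichever array was left out. MYC and OLMALINC did not, the latter lost without shRNA 1 replicate 2 (−1.82), shRNA 2 replicate 1 (−2.16) or shRNA 2 replicate 2 (−2.11). Of 11 further genes named for a difference between the shRNAs, 6 passed whichever array was left out, namely STK26, ZDHHC2, BIRC3, RELB, TNFAIP3 and FAS. Without shRNA 1 replicate 2, BCL6 (1.47), CHAC1 (1.38), PSAT1 (0.95) and TIGAR (1.07) were lost. Without shRNA 2 replicate 2, CHAC1 (1.37), PSAT1 (1.13), TIGAR (0.84) and TP53INP1 (1.70) were lost. In each named gene that passed, all 4 arrays compared lay in the direction of the change, which follows from selecting genes by the test.

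Between the shRNAs, 8 gene lists passed with the second settings. NF-kB targets were 0.79 higher with shRNA 2 (camera adjusted p = 2.22e-07, adjusted p = 0.537 with an estimated correlation), with 10 higher over all genes, 13 adjusted over the list alone. FOXO targets were 0.53 higher (adjusted p = 0.00149, adjusted p = 0.883 with an estimated correlation), with 8 higher and 2 lower over all genes, 11 and 2 adjusted over the list alone. ATF4 genes were 0.39 higher (adjusted p = 0.0116, adjusted p = 0.883 with an estimated correlation), with 6 higher and 1 lower over all genes, 8 and 1 adjusted over the list alone. CHAC1 differed by 1.67 and PSAT1 by 1.18. The p53 targets were 0.27 higher (adjusted p = 0.0253, adjusted p = 0.883 with an estimated correlation), with 9 higher over all genes and 9 adjusted over the list alone. TP53INP1 differed by 2.07, the death receptor FAS by 1.58 and TIGAR by 1.12. Histone genes were lower with shRNA 2 (−0.78, adjusted p = 2.29e-11, adjusted p = 0.153 with an estimated correlation), with 18 lower and 1 higher over all genes, 21 and 1 adjusted over the list alone. Cholesterol synthesis genes were lower (−0.60, adjusted p = 4.28e-06, adjusted p = 0.883 with an estimated correlation), with 6 lower over all genes, 10 lower and 1 higher adjusted over the list alone. G2/M genes were lower (−0.51, adjusted p = 5.52e-09, adjusted p = 0.883 with an estimated correlation), with 15 lower over all genes, 23 lower and 2 higher adjusted over the list alone. G1/S genes were lower (−0.40, adjusted p = 6.6e-07, adjusted p = 0.883 with an estimated correlation), with 10 lower and 1 higher over all genes, 13 and 2 adjusted over the list alone. The p53 list was lost without shRNA 1 replicate 1 (0.21) or shRNA 2 replicate 2 (0.14) and read 0.51 without shRNA 2 replicate 1. The ATF4 list was lost without shRNA 1 replicate 2 (0.28) or shRNA 2 replicate 1 (0.37). With the settings fixed beforehand ribosomal proteins (0.18, adjusted p = 0.000845, adjusted p = 0.804 with an estimated correlation) and immediate early genes (0.24, adjusted p = 0.0205, adjusted p = 0.606 with an estimated correlation) also passed. Their medians were −0.0077 and 0.38 with the second settings, where neither passed.

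Lists tied to the proposed roles of ZDHHC11 did not pass against control with the second settings. As the mean of both shRNAs, MYB targets had a median of −0.07, miR-150 targets 0.01, MYC targets 0.01, the ZDHHC family 0.11 and the depalmitoylating enzymes 0.19. Among stress and survival lists the medians were −0.01 for p53 targets, 0.14 for apoptosis regulators, 0.16 for the unfolded protein response and −0.04 for heat shock genes. With shRNA 2 alone the p53 median was 0.36 and did not pass (adjusted p = 0.0752), although 6 of 24 genes passed as higher, and 7 adjusted over the list alone. Among B cell lists the medians for both shRNAs were 0.12 for B cell receptor signalling, −0.03 for plasma cell genes and 0.15 for MHC class I. Among metabolic and housekeeping lists these medians were 0.0011 for glycolysis and hypoxia, 0.08 for oxidative phosphorylation, −0.04 for ribosomal proteins, 0.01 for immediate early genes, −0.06 for the small RNA machinery and −0.06 for snoRNA host genes. With shRNA 2 alone the immediate early median was 0.31 and did not pass (adjusted p = 0.0506), with 5 of 20 genes higher over all genes and 5 adjusted over the list alone. In the ZDHHC family 5 of 18 genes were higher and 2 lower with shRNA 2, over all genes as well as adjusted over the list alone. Markers of other cell types had medians of −0.34 for T cells (8 genes tested), −0.02 for NK cells (2), 0.53 for myeloid cells (5), −0.19 for erythroid cells and megakaryocytes (6) and −0.23 for fibroblasts and epithelium (5). These fold changes compare groups, so they cannot show other cells present on all arrays alike. With shRNA 2 the T cell genes CD247 (−1.25), LCK (−1.14) and LAT (−0.71) and the epithelial gene CLDN4 (−1.51) passed as lower and the myeloid integrin ITGAM (1.28) as higher over all genes.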

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

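The tests of the depth of the knock-down, of array brightness, of a single proportional response and of S phase were chosen only after the results were seen; those of RNA without a poly(A) tail and of a single control array were chosen before. Results are listed here because the effects of the 2 shRNAs against the same control differed by a test of the difference itself, or because a channel outside the comparisons held signal. With the second settings 2012 genes differed between the shRNAs, and MYC was higher with shRNA 2 than with shRNA 1 by 0.955 on the log2 scale; that difference was lost without shRNA 1 replicate 2 (0.82) or shRNA 2 replicate 2 (0.94). Median differences, shRNA 2 minus shRNA 1, were −0.783 for histone genes, −0.604 for cholesterol synthesis, −0.505 for G2/M genes, −0.397 for G1/S genes, 0.274 for p53 targets, 0.388 for ATF4 genes, 0.525 for FOXO targets and 0.786 for NF-kB targets. All 8 lists were lost with an estimated correlation (adjusted p = 0.153 for histone genes, 0.537 for NF-kB targets and 0.883 for the others). That test had little power with 3 residual degrees of freedom. The p53 list was lost without shRNA 1 replicate 1 (0.21) or shRNA 2 replicate 2 (0.14), and the ATF4 list without shRNA 1 replicate 2 (0.28) or shRNA 2 replicate 1 (0.37). In the red channel, where no sample was hybridised, up to 832 spots on an array were well above background, 1.37% of its spots, and the channel was used for no comparison. With 2 arrays per group single arrays could not be tested as outliers.

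With the second settings the response to shRNA 2 was larger than that to shRNA 1 and partly opposite. LRRC8A, RELB, TNFAIP3 and BIRC3 were lower with shRNA 1 and higher with shRNA 2. With the settings fixed beforehand 1 gene passed with shRNA 2 and 0 with shRNA 1. The size rested most on shRNA 2 replicate 2, whose log2 differences from the control arrays had an SD across probes of 0.534 and 0.567. These were 0.420 and 0.464 for shRNA 2 replicate 1 and 0.363 to 0.418 for the shRNA 1 arrays. A deeper knock-down by shRNA 2 was not seen in ZDHHC11, which read 0.58 higher with shRNA 2 (SE 0.229), though that difference did not pass. The ZDHHC11 probes may also read ZDHHC11B, and no protein was measured here, so the depth for ZDHHC11 alone is unknown. Array brightness as the whole source is argued against by quantile normalization, after which 7.23 genes still passed with shRNA 2 for each one with shRNA 1. A single response in proportion to the loss of ZDHHC11 is argued against by the 14 genes that passed in opposite directions with the second settings. With the settings fixed beforehand 0 genes passed with shRNA 1, so opposite calls could not be counted there. Off-target effects of either shRNA and differences between cultures stay open and untested, since each shRNA was read on 2 arrays and the shRNA sequences were not used here.

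Histone genes were lower with shRNA 2, a list call lost in camera with an estimated correlation (adjusted p = 0.204). A smaller share of cells in S phase may contribute, as the G1/S genes that also peak near that phase had a median of −0.36. The G1/S call was lost with an estimated correlation too, and the cell cycle was not measured. Poorer recovery of RNA without a poly(A) tail, a feature of most histone transcripts, stays open. The 206 snoRNA genes tested, which also lack the tail, had a median of −0.40, against −0.98 for histones. The −0.40 lay between the values set beforehand for and against poorer recovery. The standard error of the snoRNA mean across genes was 0.0455, which does not measure the spread between arrays. Of the snoRNA genes 42 were lower and 11 higher. Other classes without the tail were read after the results were seen. With shRNA 2, 1 of 3 ribosomal RNA genes and the 1 vault RNA gene tested passed as lower, whereas 0 of 14 small nuclear RNA genes passed. The 1 gene tested each for RNase MRP, RNase P, small cytoplasmic and telomerase RNA did not pass. As 12.6% of all genes passed with shRNA 2, classes this small cannot decide the question.

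Interferon response genes were higher with both shRNAs, led by USP18, IFIT1 and IFIT3. A low response in a single control array as the whole source is argued against, because the median of the list for both shRNAs together was 0.31 without control replicate 1 and 0.54 without control replicate 2, and the list passed each time with a preset correlation. With all arrays the call was lost with an estimated correlation (adjusted p = 0.782). Sensing of the hairpin RNA itself stays open and untested, as the control cells also carried an shRNA, whose sequence was not used here.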

How the results depend on the processing

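Tests with the second settings, with the alternatives applied to them, with background-subtracted signal on at least 2 arrays and with 1 control array for each shRNA were chosen only after the data were seen. The other alternatives were chosen before. Counts below are in the order shRNA 1, shRNA 2, mean, shRNA 2 against shRNA 1, and both shRNAs in the same direction. Starting from the settings fixed beforehand (0, 1, 0, 5 and 0), normexp gave 287, 1347, 407, 1676 and 74, the intensity trend with robust eBayes 77, 515, 57, 884 and 16, the filter on all 6 arrays 15, 174, 0, 537 and 5, and the second settings 255, 1602, 337, 2012 and 72. The shRNA 2 count became 0 with quantile normalization, the deposited table, no filter, only the groups compared, the replicate number as a block, background-subtracted signal on at least 2 arrays and any 1 array left out. The count between the shRNAs became 0 with no filter, only the groups compared, the block and any 1 array left out, and 935 with background-subtracted signal on at least 2 arrays. The correlation became 0.270 with normexp, 0.309 to 0.528 with 1 array left out and 0.0873 or 0.144 with 1 control array for each shRNA. ZDHHC11 passed at −1.70 (adjusted p = 2.08e-06) and −1.12 (adjusted p = 0.00055) with normexp, −1.20 (adjusted p = 0.0453) and −0.82 (adjusted p = 0.0473) with the filter on all 6 arrays, −1.20 (adjusted p = 0.0132) and −0.82 (adjusted p = 0.0216) with the trend, and −1.84 and −1.26 with the second settings; the ranges over alternatives were 2.08e-06 to 0.695 and 0.00055 to 0.42. Of 27 list calls, 0 remained with an estimated correlation and 0 with fry.

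Starting from the second settings, the processed signal gave 15, 174, 0, 537 and 5, its quantile normalization 0, 160, 0, 542 and 0, the deposited values 0, 165, 0, 556 and 0, the filter on at least 2 arrays 0, 0, 0, 935 and 0, and no filter 3, 0, 1, 5 and 0. The block gave 460 with shRNA 1, 622 for the mean and 137 for both, and the trend 661, 2447, 902 and, for both, 191. Only the groups compared gave 965 with shRNA 2 and 1 for the mean, normexp 565 and quantile normalization of background-subtracted signal 192 for the mean, and a log2 threshold of 1 gave 499, 129, 652 and 37 in the last 4 places. Leaving out 1 array gave 1 to 187, 36 to 1283, 6 to 350, 255 to 1952 and 0 to 52, a correlation of 0.236 to 0.439, and in these fits the lone array of a group is assumed to vary like the others. With 1 control array for each shRNA the correlation was 0.0915 or 0.163. The settings fixed beforehand gave 0, 1, 0, 5 and 0, and a correlation of 0.385. Of 22 list calls against control, 0 remained with an estimated correlation and 2 with fry; no filter gave 36. Of the 77 gene results named, none reversed under any alternative; 71 still passed with normexp, 69 with quantile normalization of background-subtracted signal, 41 with the processed signal, 31 with the deposited table, 7 with the filter on at least 2 arrays, 0 with no filter, 2 with the settings fixed beforehand and 42 to 69 with 1 array left out. Of 30 list results 30 passed with normexp and with the settings fixed beforehand, and 24 to 29 with 1 array left out.

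In simulated data, values held at the floor lowered the prior degrees of freedom to 0.714 with the filter on at least 2 arrays, where 31.3% of log2 changes of 1 were recovered, against 64.8% with the filter on all 6; for the other changes in counts the cause was not tested. The replicate numbers coincided with the slide rows, and the third principal component followed them, but the correlations of replicate differences between groups (0.182, 0.0112 and 0.202) were not high enough throughout to take the numbers as pairs. The block, which raised several counts of the second settings and lowered those fixed beforehand to 0, is therefore given only here. Any effect of slide row, which was balanced over the groups, thus stays in the spread of the fits without the block. A slide block was not run, as there was 1 slide. Signal over background limited the tests to 28042 of 58201 probes with the settings fixed beforehand and 23045 with the second settings, which leave out genes dim on any array.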

Other observations

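The values here belong to no comparison fixed beforehand, all of them were chosen after the data were seen, and no explanation was tested. Genes beside ZDHHC11 on its chromosome arm did not pass with either shRNA with the second settings. TRIP13, a checkpoint gene, changed by −0.38 and −0.14, BRD9, a chromatin gene, by 0.32 and −0.20, CEP72, a centrosome gene, by 0.25 and 0.38, and SLC12A7, an ion transporter, by 0.56 and 0.59 with shRNA 1 and shRNA 2. Genes well above background on both arrays of a group and on none of another were also counted. With shRNA 1, 64 such genes were seen only with the shRNA and 76 only in control. With shRNA 2 these counts were 151 and 47, CALD1 and LINC01882 being among the genes seen with shRNA 2 and not in control. These calls are not scaled for brightness, and the shRNA 2 arrays were the brightest in each slide row. Their 75th percentiles were 263 and 177, against 228 and 147 for control. With shRNA 2, 53 of 206 small nucleolar RNA genes (25.7%) and 1400 of 11189 protein-coding genes (12.5%) passed, a difference that was not tested, and 4 snoRNA genes passed with shRNA 1. Long non-coding RNAs passed for 106 of 970 genes with shRNA 2, 81 of them lower. MYC was lower with shRNA 1 by a log2 fold change of −0.99, a call lost without any 1 of the 6 arrays (−1.12 to −0.85), and the list of MYC targets did not pass with shRNA 1 (median −0.01, adjusted p = 0.859).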
